A study of Mus musculus with 6 samples.

How the data were processed

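Gene expression was measured in 6 breast tumours of FVB mice on an Illumina mouse bead array, 1 array per tumour. Per the labels, total RNA was extracted with Trizol and a column kit with DNase treatment, and biotin-labelled RNA was hybridised. The labels name 3 tumours as control (both Cyp27b1 alleles floxed, no Cre recombinase) and 3 as knockout (floxed with Cre). The design text speaks of triplicate mice, but no label ties a sample to an animal, so p-values measure the spread between these samples.

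The authors deposited a table of signal intensity with a detection p-value for each probe and array, without normalization, per the file headers. In 1 detection column the deposited values included entries of other content, caused by broken lines. The 4 broken lines, which belong to 2 probes, were left out and 45279 probes remained. The authors also deposited normalized values on a log2 scale. The submitters' processing notes name lumi 2.6.0, and the normalization steps are not given in the sources used here. Each column of those values had the same order of probes as the signals of its own array, with a Spearman correlation across probes of 1, and medians between 7.40 and 7.41. How the authors' values were scaled stays unknown, so they served as an alternative.

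Signals were background corrected, quantile normalized and log2 transformed with neqc in limma 3.58.1 under R 4.3.3, with an offset of 16. No control probes came with the table, so the background was inferred from the detection p-values. Probes with a detection p below 0.05 on at least 3 of the 6 arrays were kept, which left 15885 probes. The number of arrays limits the precision of every value. A log2 value compresses the changes of dim probes, because the offset and the background set a floor, which lay between 4.90 and 5.00 on the log2 scale. Where every probe of a gene was not above background on all arrays of a group, a fold is given as a lower bound. It sets the bright group's mean against the dim group's mean of, per array, the higher of the floor and the probe's own value.

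Gene symbols came from the platform annotation and were checked by gene number against the GRCm38.p6 gene table, where 34805 probes matched and 0 symbols changed. There were 34883 probes with 1 symbol, 18 with several and 10378 unnamed here, and no gene was named from a probe with several. Of 707 genes in the lists, 645 had a named probe and 418 a kept probe. The others were not analysed here.

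Knockout minus control was tested per probe with lmFit and eBayes in limma, two-sided, with Benjamini-Hochberg adjustment over the kept probes, and called at an adjusted p below 0.05. All adjusted p-values of genes come from this test. For 32 gene lists, camera in limma compared the genes of a list with all other measured genes, with a preset correlation of 0.01, on the kept probe of each gene with the highest mean. Lists with at least 5 measured genes were tested and adjusted together. A list's median is also given with members undetected in a whole group at their bound where it differs. Cyp27b1 was tested by an exact two-sided permutation test. The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined, apart from those named here and below as chosen later. Chosen after the data were seen were the alternatives without the chromosome 11 segment and for the principal components, and the tests on chromosome 11, of the normalization and of other non-epithelial markers. The rule took Cyp27b1 and the measured members of the vitamin D metabolism list, and the 12 genes with the largest rise and the 12 with the largest fall among called probes, passing over clone and predicted names. It also took the 4 members of smallest p from each called list and at most 2 from each other list. A gene named outside this rule was chosen after its values were seen.

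The tests were tested on simulated data over 15885 probes with the real means and with spreads as shrunk by eBayes. For the comparison of knockout and control, 94% of probes changed by 2 log2 units and 17% of those changed by 1 unit were called, and 7 of 118 calls were of unchanged probes. Such shares depend on how many probes change. The real data gave 1461 calls, so the shares may differ there. For the gene lists, the shifted list and 0 of 50 unshifted lists were called. The simulated probes were independent of each other, while the estimated correlation between genes was 0.65 in the real matrix list. The simulation therefore cannot tell how often camera calls an unshifted list of correlated genes. A search for runs of neighbouring genes, simulated over 9338 genes, put 32 windows past its limit inside a raised run and 0 outside it.

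The search took the running median of log2 changes over 15 genes in the order of GRCm38.p6 and compared it with 1000 shuffled orders, and was chosen after the data were seen.

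The alternatives were the authors' values, no background correction, an offset of 50, cyclic loess, median scaling, no filter, a filter of detection p below 0.01 on all 6 arrays, eBayes with trend and robust settings, array weights, the replicate number as a block, each tumour left out in turn, the mean of a gene's probes, camera with an estimated correlation, and fry, which tests whether the genes of a list move on balance one way and does not compare them with other genes. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.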

Results

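The series profiled breast tumours of mice in which the mammary epithelium lacks Cyp27b1, the enzyme that makes the active form of vitamin D, and of mice that keep it. The question was how tumour gene expression differs without local production of active vitamin D. Only the knockout tumours carried Cre, so an effect of Cre itself cannot be told apart from that of losing Cyp27b1. There were 3 control and 3 knockout tumours. The summed signal of an array was 1.34e7, 1.29e7 and 1.07e7 in control tumours 1, 2 and 3, and 1.48e7, 1.23e7 and 1.26e7 in knockout tumours 1, 2 and 3. Between 33.4% and 36.1% of the 45279 probes were above background on an array.

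Cyp27b1 itself was not above background in any tumour. Its only probe had a normalized log2 value of 4.34 ± 0.05 (SD, n = 3) in the control and 4.36 ± 0.07 (SD, n = 3) in the knockout tumours. The log2 difference was 0.02 (exact two-sided permutation p = 0.80, where 3 against 3 tumours cannot go below 0.10). The probe therefore checks nothing about the deletion, and its place relative to the deleted part is not given in the sources used here. Vdr, the vitamin D receptor, rose from 8.73 ± 0.81 to 10.72 ± 0.50 (SD, n = 3 each) in the knockout tumours, a log2 change of 2.00 ± 0.43 (SE, limma adjusted p = 0.028). Luminal markers were higher and matrix genes lower in the same tumours (median log2 changes 1.61 and -2.72). Whether the rise of Vdr follows the mix of cells was not tested.

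Of the 7 measured genes of vitamin D metabolism and signalling, Vdr was the 1 gene called over all genes, and 2 rose when adjusted over the list alone. Rxra, the partner of the receptor, had a log2 difference of 0.66 (adjusted p = 0.067). The log2 differences of Rxrb (0.31), Med1 (0.27), Dhcr7 (0.25), Pdia3 (0.08) and Cyp27a1 (-0.42) were not called. Cyp24a1, the enzyme that degrades active vitamin D and a standard target of the receptor, was not above background on any array. The list as a whole was not called by camera (median log2 change 0.27, adjusted p = 0.24), while fry, which does not compare it with other genes, called it higher (adjusted p = 0.037). Of the 3 kept probes of Vdr 2 were called, and all 3 gave 1.99 to 2.06. The call was lost for Vdr without control 2 (0.067), control 3 (0.065), knockout 1 (0.051), knockout 2 (0.052) or knockout 3 (0.066), range over the alternatives 0.019 to 0.12, the highest of these without the filter on dim probes.

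Among 14 measured target genes of the vitamin D receptor, 4 rose and 2 fell over all genes, and 5 and 2 when adjusted over the list alone. Igfbp5, a secreted binding protein of insulin-like growth factors, rose by 2.45 ± 0.28 log2 units (SE, adjusted p = 0.0038). Cdkn1a, which encodes the cell cycle inhibitor p21, fell by 1.04 on the log2 scale (SE 0.21, adjusted p = 0.024). The other rises were those of Cebpb, Lrp5 and Cdh1, which the list of luminal markers also holds, and the other fall that of Slc8a1, all named after their values were seen. The list was not called (median log2 change 0.59, or 0.54 with the gene undetected in a whole group at its bound, camera, adjusted p = 0.28). Leaving out a tumour ended the call of Cdkn1a without control 1 (0.081), control 2 (0.066), control 3 (0.061) or knockout 3 (0.069), range over the alternatives 0.0070 to 0.081.

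The knockout tumours differed widely from the control tumours. Kit, a receptor of luminal progenitor cells, was 5.28 ± 1.00 (SE) log2 units higher, and Elf5, a transcription factor of the alveolar lineage, 3.46 ± 0.34 (SE) higher, or 1.36 with the authors' values. Cemip, which takes part in the breakdown of hyaluronan, fell by 6.48 log2 units (SE 0.50), and Tagln, an actin-binding protein of smooth muscle and myofibroblasts, fell by 4.93 on the log2 scale (SE 0.48).

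**Figure D1:**
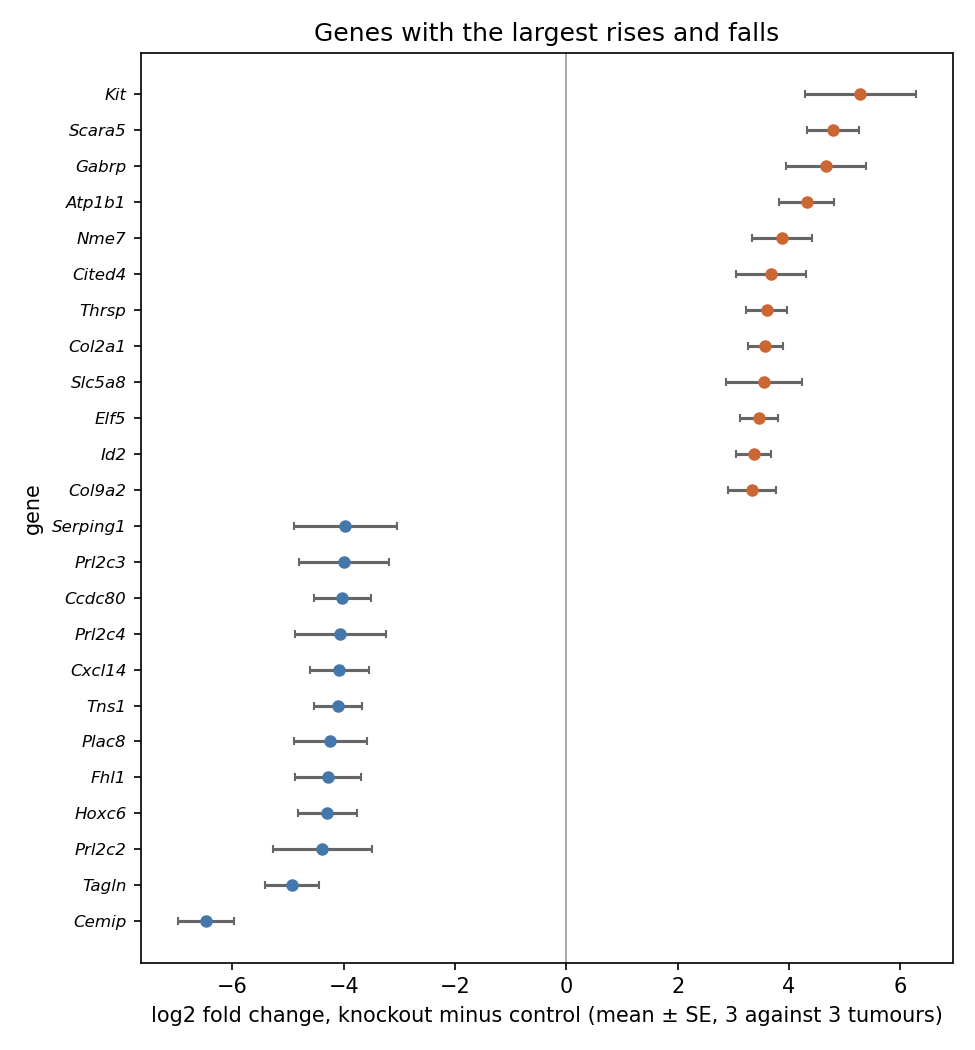
The horizontal axis gives the log2 fold change of knockout minus control for the 12 genes with the largest rise (orange) and the 12 with the largest fall (blue), as points with bars of 1 SE from 3 against 3 tumours. The values run from -6.48 for Cemip to 5.28 for Kit.

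In limma, 1461 of the 15885 kept probes passed an adjusted p of 0.05, 657 higher and 804 lower in the knockout tumours. They stood for 459 gene symbols higher and 571 lower, with 135 called probes not tied to 1 symbol. Changes of at least 2 log2 units were called for 125 probes higher and 341 lower. At an unadjusted p below 0.05 there were 3923 probes, where chance alone gives 794. The groups did not overlap at 4798 kept probes (30.2%), where chance gives 10%. On the first principal component, with 56.6% of the variance, the control tumours lay between -63.4 and -33.3 and the knockout tumours between 35.8 and 57.5. On the second, with 18.4%, knockout 1 lay at 53.5 and knockout 2 and 3 at -26.2 and -31.5. The count of called probes was 476 without control 1, 741 without control 3 and 568 without knockout 2, and 723 without the filter. Of 29 gene lists tested, camera called 2 higher and 6 lower, and 0 with an estimated correlation, where fry called 9.

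The other genes with the largest rises included Scara5, a scavenger receptor (log2 change 4.79 ± 0.47 SE), and Gabrp, a subunit of the GABA-A receptor (4.67 ± 0.72 SE). Atp1b1, a subunit of the sodium pump, rose by 4.32 and Slc5a8, a transporter of short-chain fatty acids and lactate, by 3.55 log2 units. Cited4 rose by 3.68 and Id2, an inhibitor of helix-loop-helix factors, by 3.36. The cartilage collagens Col2a1 and Col9a2 rose by 3.58 and 3.34. Thrsp, a regulator of fatty acid synthesis, was not above background in the control tumours and was at least 10.7-fold higher in the knockout tumours (adjusted p = 0.0032), a bound that holds only with the background correction used here, since its log2 change of 3.60 was 1.40 with the authors' values. Nme7 gave 3.87, but it neighbours and overlaps Atp1b1 in GRCm38.p6 and its 7 kept probes ranged from -0.34 to 3.87, with 3 called, so its rise is uncertain. Other probes of Kit and Elf5 gave rises down to 1.65 and 1.11. Kit lay at 4.64, 9.03 and 5.55 in the control tumours and at 12.16, 11.82 and 11.07 in the knockout tumours. Adjusted p-values passed 0.05 for Kit without control 1 (0.063), control 3 (0.067) or knockout 2 (0.067), range over the alternatives 0.0054 to 0.099, Gabrp without control 1 (0.051), range over the alternatives 0.0036 to 0.057, Slc5a8 without control 1 (0.051) or knockout 2 (0.073), range over the alternatives 0.0073 to 0.10, and Cited4 without knockout 2 (0.052), range over the alternatives 0.0073 to 0.073.

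The other large falls were those of Hoxc6, a homeobox gene (log2 change -4.29 ± 0.52 SE), Fhl1 (-4.28), Plac8 (-4.24), Tns1, which ties actin to adhesion sites (-4.10), the chemokine Cxcl14 (-4.08), Ccdc80 (-4.02) and Serping1, an inhibitor of complement C1 (-3.97). The prolactin family genes Prl2c2, Prl2c4 and Prl2c3 gave -4.38, -4.06 and -3.99. They are near-identical copies that probes may not tell apart, so which of them changed is uncertain. Another probe of Cemip gave -1.66 and another of Ccdc80 gave -0.75, both also called, and another of Prl2c2 gave -2.29, not called. Over the 71 called genes that the rule names, in all lists, 38 kept the call when each tumour in turn was left out. Without control 1 the call was lost for 28 of them, without knockout 2 for 24, and without the filter for 33. With the authors' values 45 of the 71 log2 changes shrank by more than 1.5 times and 17 calls were lost, and without background correction 32 shrank and 12 calls were lost. The losses here were of Serping1 without control 1 (0.12), control 2 (0.056), control 3 (0.12) or knockout 2 (0.10), range over the alternatives 0.011 to 0.16, Plac8 without control 1 (0.0502), range over the alternatives 0.0024 to 0.068, Prl2c2 without control 2 (0.052), control 3 (0.062), knockout 2 (0.081) or knockout 3 (0.061), range over the alternatives 0.0063 to 0.12, Prl2c4 without control 2 (0.053), knockout 2 (0.079) or knockout 3 (0.057), range over the alternatives 0.0093 to 0.11, and Prl2c3 without control 2 (0.053), knockout 2 (0.082) or knockout 3 (0.059), range over the alternatives 0.0099 to 0.11.

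Markers of luminal mammary epithelium were higher as a list (camera, adjusted p = 2.8e-09, and adjusted p = 0.49 with an estimated correlation). Of 16 measured markers, 10 rose and 6 did not pass over all genes, and 13 rose when adjusted over the list alone (median log2 change 1.61). Besides Elf5, these were led by Grhl2 (2.15 ± 0.32 SE), Esrp1 (1.79 ± 0.24 SE) and Gata3 (1.67 ± 0.21 SE), all regulators of epithelial identity. The keratins Krt8 (0.94) and Krt18 (1.15), named after their values were seen, did not pass. The mean of the list lay 1.75, 1.75 and 1.32 log2 units above the control mean in knockout tumours 1, 2 and 3. The median of the list ran from 0.96 to 1.74 over the alternatives.

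Genes of collagens and matrix, which mark fibroblasts, were lower as a list (camera, adjusted p = 2.2e-10, and adjusted p = 0.49 with an estimated correlation). Of 17 measured, 10 fell and 7 did not pass, and 15 fell when adjusted over the list alone (median log2 change -2.72). Loxl1, an enzyme of the lysyl oxidase family, gave -3.92 ± 0.58 (SE), the receptor Pdgfrb -2.77 ± 0.29 (SE), Gsn -2.52 ± 0.27 (SE) and Col3a1 -1.70 ± 0.20 (SE). Genes of the epithelial-mesenchymal transition were also lower as a list (camera, adjusted p = 4.9e-10, and adjusted p = 0.49 with an estimated correlation), with 10 of 21 measured lower and 11 not passing, and 17 lower when adjusted over the list alone (median -2.18). Among them were the transcription factors Zeb1 (-3.09 ± 0.41 SE) and Zeb2 (-2.84 ± 0.24 SE), the receptor kinase Axl (-2.18 ± 0.30 SE) and the integrin Itga5 (-3.18 ± 0.53 SE). Other probes gave -0.32 for Zeb2 and -0.68 for Axl, neither called. Over the alternatives the median of the matrix list ran from -3.26 to -1.64 and that of the transition list from -2.77 to -1.49. The call was lost for Loxl1 without the filter (adjusted p = 0.051) and for Itga5 without control 1 (0.059), range over the alternatives 0.0041 to 0.065.

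**Figure D2:**
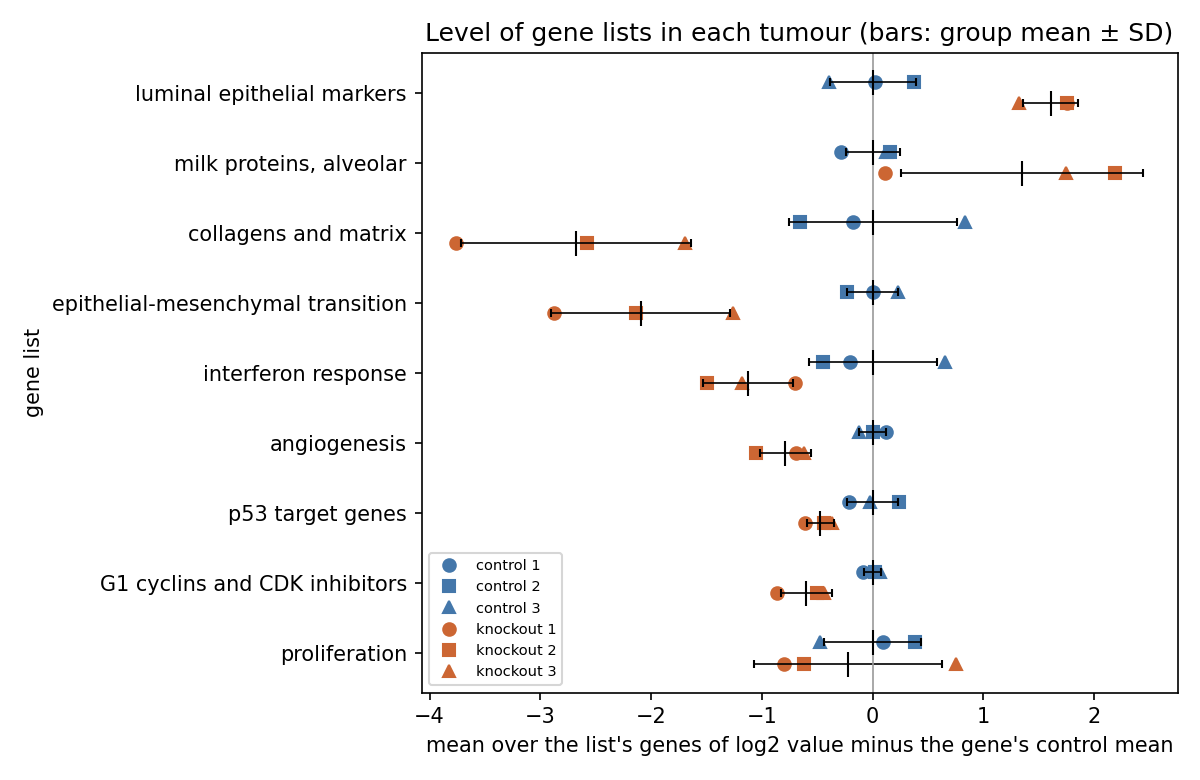
The horizontal axis gives, for 9 gene lists, the mean over the genes of a list of the log2 value minus the control mean of the gene, as 1 point per tumour with bars of the group mean ± SD. The matrix genes lie at -3.76, -2.58 and -1.70 in knockout tumours 1, 2 and 3, and the luminal markers at 1.75, 1.75 and 1.32.

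Markers of basal and myoepithelial cells went both ways. Of 13 measured, 2 rose and 4 fell, and 3 and 5 when adjusted over the list alone (median log2 change -0.11, camera, adjusted p = 0.32). The contractile genes Tagln and Myh11 fell, Myh11 by 3.17 on the log2 scale (SE 0.28, adjusted p = 0.0031). The other falls were those of Actg2 and Acta2 and the rises those of Krt14 and Itgb4, named after their values were seen. Itgb4 (1.56) lies in the raised segment of chromosome 11 described below. The matrix genes of fibroblasts fell in the same tumours (median -2.72), and which cells the contractile genes came from was not tested.

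Milk protein and alveolar genes were higher as a list, with a median log2 change of 1.18 over 12 measured genes (camera, adjusted p = 0.029, and adjusted p = 0.49 with an estimated correlation), and by fry the call was lost (adjusted p = 0.10). Luminal markers were higher and matrix and endothelial markers lower in the same tumours (medians 1.61, -2.72 and -1.60). The endothelial median rests on 4 markers, too few to test, and was -0.036 without the filter. Medians of the other non-epithelial types ran from -0.99 (muscle) to 1.18 (neutrophil and mast cell). The latter list had 5 measured genes, Kit among them, and was not called (camera, adjusted p = 0.55). Its median was -0.0068 without the filter. Over the alternatives the median of the milk list ran from 0.54 to 1.28. Stat5a, which drives alveolar differentiation, was the 1 member called over all genes (1.45 ± 0.35 SE, adjusted p = 0.043), and 3 rose when adjusted over the list alone. The log2 differences of Muc1 (1.67), Btn1a1 (1.31) and Aqp5 (1.04) were not called. The mean of the list lay 0.12 above the control mean in knockout 1, and 2.19 and 1.75 above it in knockout 2 and 3. The casein gene Csn1s1, named after its values were seen, had log2 values of 4.96, 13.67 and 13.32 in these tumours. The list lost its call without control 2 (0.052) or knockout 2 (0.079), range over the alternatives 1.1e-04 to 0.49. Calls of members changed for Stat5a without control 1 (0.15), control 2 (0.11), knockout 2 (0.14) or knockout 3 (0.11), range over the alternatives 0.0084 to 0.15, and for Muc1 without knockout 1 (0.020), range over the alternatives 0.020 to 0.23.

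Interferon response genes were lower as a list by camera, but not by fry (adjusted p = 0.11). Of 22 measured, 4 fell and 18 did not pass, and 8 fell when adjusted over the list alone (median log2 change -0.80, camera, adjusted p = 4.4e-05, and adjusted p = 0.49 with an estimated correlation). Matrix and endothelial markers of other cell types were lower in the same tumours (medians -2.72 and -1.60, the latter over only 4 markers and -0.036 without the filter). The medians of immune markers were -0.78 for MHC class II and dendritic, -0.32 for macrophage and -0.25 for T and NK cells. They were -0.05 for B and plasma cells and 1.18 for neutrophils and mast cells, and camera called none of these lists. The median of the interferon list was -0.36 without control 3 and ran from -1.15 to -0.28 over the alternatives. The falls were those of Ifit3 (-3.62 ± 0.57 SE), Isg15, a ubiquitin-like protein (-3.18 ± 0.64 SE), Oasl2 (-2.35 ± 0.43 SE) and Gbp3 (-1.70 ± 0.40 SE). Another probe of Oasl2 gave -0.93, not called. Ifit3 lost its call with the authors' values (log2 change -1.50, adjusted p = 0.11), without background correction (-1.87, adjusted p = 0.070) and without the filter (adjusted p = 0.059), range over the alternatives 0.0023 to 0.11. Adjusted p-values passed 0.05 for Isg15 without control 1 (0.089), control 3 (0.072), knockout 2 (0.071) or knockout 3 (0.057), range over the alternatives 0.0060 to 0.11, Oasl2 without control 1 (0.052) or control 3 (0.052), range over the alternatives 0.0076 to 0.078, and Gbp3 without control 1 (0.065), control 2 (0.053), knockout 2 (0.13) or knockout 3 (0.085), range over the alternatives 0.026 to 0.14.

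Genes of angiogenesis were lower as a list by camera (adjusted p = 0.030, and adjusted p = 0.49 with an estimated correlation). Of 16 measured, 5 fell and 11 did not pass, with 5 when adjusted over the list alone (median log2 change -0.58). The growth factor Fgf2 was not above background in the knockout tumours and was at least 2.67-fold lower (adjusted p = 0.0041), a bound that holds only with the background correction used here, since its log2 change was -0.53 with the authors' values. The receptor Nrp1 gave -3.03 ± 0.49 (SE), Vegfa, the vascular growth factor, -1.50 ± 0.31 (SE), and Thbs1, an inhibitor of vessel growth, -2.30 ± 0.37 (SE), its call lost without the filter (adjusted p = 0.053). Thbs2, named after its values were seen, was the other fall. Endothelial and matrix markers were lower in the same tumours. The median was -1.60 over 4 endothelial markers, 3 of them lower when adjusted over the list alone, and -2.72 over the matrix genes of fibroblasts. The endothelial markers were too few to test, and their median was -0.036 without the filter. For the other non-epithelial cell types medians ran from -0.99 (muscle) to 1.18 (neutrophil and mast cell). The median of the angiogenesis list was -0.36 without control 1 and ran from -0.76 to -0.18 over the alternatives. The list lost its call without control 2 (0.063) or knockout 2 (0.057), range over the alternatives 0.0036 to 0.49. Its members' calls ended for Nrp1 without control 1 (0.057), range over the alternatives 0.0032 to 0.061, and Vegfa without control 1 (0.069), control 2 (0.060), control 3 (0.078) or knockout 2 (0.080), range over the alternatives 0.0076 to 0.081.

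Cyclins, CDK inhibitors and p53 targets were lower as lists by camera, and each had an adjusted p = 0.49 with an estimated correlation. By fry the p53 list lost its call (adjusted p = 0.10). Matrix and endothelial markers were lower in the same tumours (medians -2.72 and -1.60, the latter over only 4 markers and -0.036 without the filter). Other non-epithelial cell types had medians from -0.99 (muscle) to 1.18 (neutrophil and mast cell), with 0.01 for adipocyte markers. Of 15 measured G1 cyclins and CDK inhibitors, 3 fell and 12 did not pass, with 3 when adjusted over the list alone (median log2 change -0.54, camera, adjusted p = 0.045, and adjusted p = 0.49 with an estimated correlation). They were the cyclin Ccnd2 (-3.59 ± 0.47 SE) and the inhibitors Cdkn2b (-1.38 ± 0.23 SE) and Cdkn1a, while Cdkn2d (-0.55) was not called. Of 17 measured p53 targets, 4 fell and 13 did not pass, and 5 fell when adjusted over the list alone (median -0.44, camera, adjusted p = 0.044, and adjusted p = 0.49 with an estimated correlation). They were Pmaip1, a promoter of apoptosis (-2.34 ± 0.45 SE), Mdm2, the p53 inhibitor (-1.21 ± 0.24 SE), Plk2 (-1.18 ± 0.30 SE) and Cdkn1a. Another probe of Pmaip1 gave -0.44, not called. The G1 list lost its call without control 2 (0.089), control 3 (0.056) or knockout 1 (0.17), range over the alternatives 0.019 to 0.49, and the p53 list without control 2 (0.17), control 3 (0.056) or knockout 1 (0.12), range over the alternatives 0.0086 to 0.49. The p53 median was -0.24 without knockout 1 and -0.28 without control 2, and over the alternatives it ran from -0.49 to -0.086 and the G1 median from -0.61 to -0.24. Members' calls ended for Cdkn1a without control 1 (0.081), control 2 (0.066), control 3 (0.061) or knockout 3 (0.069), range over the alternatives 0.0070 to 0.081, Cdkn2b without control 1 (0.061) or knockout 2 (0.052), range over the alternatives 0.0053 to 0.067, Pmaip1 without control 1 (0.072), knockout 2 (0.070) or knockout 3 (0.0501), range over the alternatives 0.0081 to 0.11, Mdm2 without control 1 (0.065), control 2 (0.052), control 3 (0.070), knockout 2 (0.079) or knockout 3 (0.057), range over the alternatives 0.0078 to 0.079, and Plk2 without control 1 (0.15), control 2 (0.12), knockout 1 (0.094) or knockout 2 (0.15), range over the alternatives 0.025 to 0.16.

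Proliferation genes, which mark dividing cells, were not called as a list. In limma 0 of 25 measured were called, 0 when adjusted over the list alone and 2 at an unadjusted p below 0.05 (median log2 change -0.19, camera, adjusted p = 0.28). Ccne1 (-1.12) and Rrm1 (-0.89) had the smallest p-values. The mean of the list lay at -0.80, -0.62 and 0.76 in knockout tumours 1, 2 and 3. The list was called lower without knockout 3 (median -0.73) and without control 3 (median -0.49), with adjusted p-values 0.046 without control 3, 6.9e-06 without knockout 3, range over the alternatives 6.9e-06 to 0.94. These camera tests preset a correlation of 0.01, while the estimate for this list over all 6 tumours was 0.76. Such small p-values therefore do not measure the spread between tumours. Camera with the estimated correlation gave an adjusted p = 0.93 over all 6 tumours. Calls were gained for Ccne1 without knockout 3 (0.020), range over the alternatives 0.020 to 0.21, and for Rrm1 without knockout 3 (0.031), range over the alternatives 0.031 to 0.47.

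Among genes of apoptosis and survival, 2 of 20 rose and 1, Pmaip1, fell, with 2 each when adjusted over the list alone (median log2 change 0.17, camera, adjusted p = 0.55, while fry called the list higher, adjusted p = 0.037). Bcl2, which protects from apoptosis, rose by 1.35 ± 0.19 (SE), and Bik, which promotes it, by 2.03 ± 0.32 (SE). The call of Bik was lost with the authors' values (log2 change 0.69, adjusted p = 0.052). Other probes gave 0.96 for Bcl2 and -0.44 for Pmaip1, neither called. Among NF-kB targets, 1 of 22 rose and 4 fell, and 3 and 4 when adjusted over the list alone. The list's median was 0.18, its mean -0.29 and its test direction lower (camera, adjusted p = 0.85). The cytokine genes Csf1 (-2.68 ± 0.26 SE) and Ccl2 (-3.08 ± 0.68 SE) fell. Nfkbia was the rise and Il1a and Vcam1 the other falls, named after their values were seen. Calls ended for Pmaip1 without control 1 (0.072), knockout 2 (0.070) or knockout 3 (0.0501), range over the alternatives 0.0081 to 0.11, and Ccl2 without control 1 (0.059), control 2 (0.052), control 3 (0.053) or knockout 2 (0.069), range over the alternatives 0.0079 to 0.14.

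Lipid and energy metabolism changed in a few genes. Of 13 fatty acid synthesis genes, 2 rose and 11 did not pass, with 2 when adjusted over the list alone (median log2 change 0.16, camera, adjusted p = 0.14). They were Thrsp and Srebf1, a regulator of lipid synthesis (2.23 ± 0.28 SE). The list was called higher without control 1 (0.026) or knockout 3 (0.039), range over the alternatives 0.026 to 0.74. Of 23 genes of hypoxia and glycolysis, 2 rose and 3 fell, and 3 and 4 when adjusted over the list alone (median -0.17, camera, adjusted p = 0.80). Aldoc, an aldolase, rose by 3.17 ± 0.22 (SE), and P4ha1, a collagen prolyl hydroxylase, fell by 2.09 (SE 0.35). Car9 was the other rise and Slc16a3 and Vegfa the other falls, Car9 and Slc16a3 named after their values were seen. Calls ended for P4ha1 without control 1 (0.052), range over the alternatives 0.0050 to 0.057, and Vegfa without control 1 (0.069), control 2 (0.060), control 3 (0.078) or knockout 2 (0.080), range over the alternatives 0.0076 to 0.081. In limma 0 of 14 cholesterol synthesis genes were called, 0 adjusted over the list alone and 2 unadjusted (median 0.03, camera, adjusted p = 0.89). Mvk gave -1.02 and Sqle 0.93, and calls were gained for Mvk without control 2 (0.034), range over the alternatives 0.034 to 0.18, and Sqle without knockout 3 (0.045), range over the alternatives 0.045 to 0.26. Of 28 oxidative phosphorylation genes limma called 0, with 0 adjusted over the list alone and 2 unadjusted (median 0.01, camera, adjusted p = 0.87), among them Uqcrq (0.56) and Ndufb3 (-0.46). Of 18 ribosomal protein genes it called 0, with 0 adjusted over the list alone and 0 unadjusted (median -0.00258, camera, adjusted p = 0.85), among them Rps14 (-0.19) and Rps24 (-0.31, its probes running from -0.31 to 0.32).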

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

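The alternatives with the segment of chromosome 11 left out and those for the principal components were chosen after seeing the data, and all others were planned. Over the alternatives the first principal component held 51.7% to 65.0% of the variance, and the log2 difference of Cyp27b1 ran from 0.00050 to 0.061. Median scaling moved the median log2 change of all probes from 0.05 to 0.16, and signal over background limits what dim probes can show.

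Called probes numbered 723 without the filter, where more probes are tested, and 476 to 1564 with each tumour left out. With the mean of a gene's probes, where 1 value per gene is tested, 968 genes were called (2455 at an unadjusted p below 0.05). Called lists numbered 0 with an estimated correlation and 5 to 10 with each tumour left out. By fry, milk (adjusted p = 0.10), interferon (adjusted p = 0.11) and p53 lists (adjusted p = 0.10) lost their calls, and vitamin D metabolism, apoptosis, MHC class II (adjusted p = 0.037 each) and T and NK cell lists (adjusted p = 0.041) gained one. The muscle list gained a call with median scaling (adjusted p = 0.015) and without the filter (adjusted p = 0.019). The G1 list lost its call with cyclic loess (adjusted p = 0.051), array weights (0.12) and the mean of probes (0.080), the p53 list with median scaling (0.053) and array weights (0.12), and the milk list with the stricter filter (0.15). With the replicate number as a block, 1381 probes and 8 lists were called, and of the named genes 4 lost and 4 gained a call. Correlations of the deviations were 0.23, 0.088 and 0.061 for same-number tumours of the 2 groups and -0.20 to 0.075 for the others. In the other group, 5 of 6 tumours were closest to their own number. With 3 tumours per group these values cannot tell whether same-number tumours are pairs. Without the segment of chromosome 11, 1449 probes were called.

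Lists not called reversed the sign of their median, and the cause was not tested. With the authors' values ribosomal proteins gave 0.035. Cyclic loess gave -0.067 for adipocyte, -0.029 for cholesterol, -0.025 for oxidative phosphorylation, 0.046 for ribosomal, -0.045 for endoplasmic reticulum stress and -0.011 for growth factor genes. Median scaling gave 0.0066 for B and plasma cell, 0.082 for ribosomal and 0.0076 for immediate early genes. Without the filter the values were -0.028 for NF-kB, 0.018 for MHC class II, 0.015 for B and plasma cell, -0.0068 for neutrophil, 0.028 for hypoxia and -0.00480 for oxidative phosphorylation genes. The stricter filter gave 0.12 for basal and -0.023 for endoplasmic reticulum stress genes. With too few genes left to test, it also gave 0.90 for macrophage, 0.91 for B and plasma cell and -0.29 for skin keratinocyte markers. Array weights gave 0.099 for B and plasma cell, 0.16 for hypoxia and -0.00289 for oxidative phosphorylation genes. The mean of a gene's probes gave -0.00480 for oxidative phosphorylation, 0.0040 for ribosomal genes and 0.094 for Rps24, whose probes differ in sign.

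With each tumour left out in turn, medians ran from -0.73 to 0.12 for proliferation, -0.25 to 0.49 for NF-kB, -0.36 to 0.094 for basal, -0.28 to 0.40 for adipocyte, -0.58 to 0.058 for macrophage, -0.14 to 0.13 for B and plasma cell, -0.34 to 0.15 for hypoxia, -0.057 to 0.30 for cholesterol, -0.029 to 0.11 for oxidative phosphorylation, -0.040 to 0.079 for ribosomal, -0.14 to 0.19 for endoplasmic reticulum stress, -0.25 to 0.27 for immediate early and -0.072 to 0.092 for growth factor genes, and -0.016 to 0.090 for Hbb-bs.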

Other observations

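The tests on chromosome 11, of normalization and of other non-epithelial markers were chosen only after the result was seen, while the splits of the samples and the test on luminal markers were planned.

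Means over muscle, endothelial, T and NK cell, and MHC class II and dendritic markers were lower in each knockout tumour than in any control tumour. Relative to the control mean, endothelial markers lay at -2.09, -1.67 and -1.37 in knockout 1, 2 and 3 and at -0.55 or above in the controls. Muscle markers lay at -1.34, -1.06 and -1.06 and at -0.63 or above. T and NK cell markers lay at -0.74, -0.58 and -0.51 and at -0.16 or above. MHC class II and dendritic markers lay at -0.38, -0.58 and -0.43 and at -0.23 or above. Means over adipocyte, macrophage, B and plasma cell, neutrophil and mast cell, red blood cell and skin keratinocyte markers overlapped between the groups. Of 7 skeletal muscle markers, 1 fell and 6 did not pass, with 4 lower when adjusted over the list alone (median log2 change -0.99, camera, adjusted p = 0.058). Des, an intermediate filament of muscle, fell by 2.41 on the log2 scale (SE 0.40, adjusted p = 0.012), and Acta1 gave -2.66. The muscle gene Myl1, named after its values were seen, lay at 10.61 in control 3 and between 4.40 and 4.74 in the other tumours. Of 8 adipocyte markers 1 rose and 2 fell, with 1 and 2 when adjusted over the list alone (median 0.01, mean -0.23, test direction lower, camera, adjusted p = 0.85). Lpl, lipoprotein lipase, gave -3.43 ± 0.47 (SE), Agpat2 1.09 ± 0.19 (SE), and Aoc3, named after its values were seen, was the other fall. Of 4 measured endothelial markers, too few to test, 1 fell, and 3 when adjusted over the list alone (median -1.60, and -0.036 without the filter, where camera gave an adjusted p = 0.20). It was Eng, a co-receptor of vessel cells (-2.95 ± 0.30 SE), and Egfl7 gave -1.49. Hbb-bs, the 1 red blood cell gene measured, gave 0.04 and was not called, with 0 adjusted over the list alone and 0 unadjusted in limma. Of 4 skin keratinocyte markers, also too few to test, 1 fell, with 1 when adjusted over the list alone (median 0.16, mean -0.18), Ivl (-1.84 ± 0.35 SE), and Krt10 gave -0.29. The muscle list was called lower with median scaling (0.015), without the filter (0.019), and without control 1 (0.026) or control 2 (0.017), range over the alternatives 0.015 to 0.49. Calls changed for Des without control 1 (0.056), range over the alternatives 0.0058 to 0.057, Agpat2 without control 1 (0.054) or knockout 2 (0.062), range over the alternatives 0.0091 to 0.062, and Ivl without control 1 (0.070) or knockout 2 (0.072), range over the alternatives 0.0078 to 0.083, and were gained for Acta1 without knockout 2 (0.036), range over the alternatives 0.036 to 0.26, and Egfl7 without control 2 (0.024), range over the alternatives 0.024 to 0.18.

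Immune cell markers were not called as lists by camera, while fry called the MHC class II and dendritic list (adjusted p = 0.037) and the T and NK cell list (adjusted p = 0.041) lower. Of 7 T and NK cell markers 1 fell, with 2 lower when adjusted over the list alone (median log2 change -0.25, camera, adjusted p = 0.18). It was Thy1, which fibroblasts also express and the matrix list also holds (-3.02 ± 0.55 SE). Cd3e, not above background in the knockout tumours, was not called. Of 5 MHC class II and dendritic markers 1 fell, with 1 when adjusted over the list alone (median -0.78, camera, adjusted p = 0.28), H2-DMa (-1.06 ± 0.26 SE), and H2-DMb1 gave 1.06. Another probe of H2-DMa gave -0.78, not called. Of 5 neutrophil and mast cell markers Kit rose, with 1 higher and 1 lower when adjusted over the list alone (median 1.18, camera, adjusted p = 0.55), and Mmp9 gave -2.34. In limma 0 of 7 macrophage markers were called, 1 adjusted over the list alone and 2 unadjusted (median -0.32, camera, adjusted p = 0.85), and Cd14 gave 2.602 and Lgals3 0.90. In limma 0 of 5 B and plasma cell markers were called, 1 adjusted over the list alone and 1 unadjusted (median -0.05, mean 0.22, test direction higher, camera, adjusted p = 0.63), and Xbp1 gave 0.91 and Ms4a1 0.45. Calls changed for Kit without control 1 (0.063), control 3 (0.067) or knockout 2 (0.067), range over the alternatives 0.0054 to 0.099, Thy1 without control 1 (0.060) or control 3 (0.059), range over the alternatives 0.0040 to 0.081, and H2-DMa without control 1 (0.15), control 2 (0.065), control 3 (0.13), knockout 2 (0.15) or knockout 3 (0.12), range over the alternatives 0.014 to 0.15, and were gained for H2-DMb1 without knockout 3 (0.034), range over the alternatives 0.034 to 0.32, Cd14 without control 3 (0.033) or knockout 1 (0.026), range over the alternatives 0.013 to 0.19, and Xbp1 without knockout 1 (0.022), range over the alternatives 0.022 to 0.20.

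Signalling and stress lists were not called by camera either. Among 18 genes of growth factor signalling, Pik3r1, a regulatory subunit of PI3K, rose by 1.30 ± 0.31 (SE) and Igf1, insulin-like growth factor, fell by 2.16 (SE 0.53), with 1 each when adjusted over the list alone (median log2 change 0.03, camera, adjusted p = 0.78). Among 18 genes of endoplasmic reticulum stress, Ddit3 fell by 1.60 (SE 0.36), with 1 when adjusted over the list alone (median 0.04, mean -0.03, test direction lower, camera, adjusted p = 0.85). Among 15 immediate early genes, Egr2 fell by 2.70 (SE 0.47), with 1 when adjusted over the list alone (median -0.02, camera, adjusted p = 0.85), and Fos gave 1.09. Another probe of Igf1 gave -1.58, not called. Calls ended for Pik3r1 without control 1 (0.078), control 2 (0.10), control 3 (0.11), knockout 2 (0.13) or knockout 3 (0.10), range over the alternatives 0.0091 to 0.13, Igf1 without control 1 (0.11), control 2 (0.053), control 3 (0.12), knockout 1 (0.065) or knockout 2 (0.12), range over the alternatives 0.014 to 0.17, Ddit3 without control 1 (0.13), control 2 (0.080), control 3 (0.078), knockout 2 (0.12) or knockout 3 (0.088), range over the alternatives 0.0045 to 0.13, and Egr2 without control 1 (0.066) or knockout 2 (0.052), range over the alternatives 0.0065 to 0.070, and one was gained for Fos without knockout 3 (0.029), range over the alternatives 0.029 to 0.34.

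The 10 splits of the 6 tumours into groups of 3 are too few for a share under 0.05. The real split called 1461 probes and the highest of the others 1, so 1 of the 10 gave as many. At an unadjusted p below 0.05 the real split gave 3923 and the highest other 979, again 1 of 10. For gene lists the real split called 8 and the highest other 12, with control 1, knockout 1 and knockout 2 on one side, and 4 of the 10 splits gave as many.

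Matrix genes were lower and luminal genes higher in the knockout tumours. Over 5 other normalizations or background corrections the highest adjusted camera p of both lists was 1.6e-08. This p cannot decide whether the normalization between arrays is the cause. Camera sets a list against all other genes, so a shift shared by all genes cancels. It also used the preset correlation, while with the estimated one (0.65 for matrix genes) both adjusted p-values were 0.49. Over all alternatives the median log2 change ran from -3.26 to -1.64 for matrix genes and from 0.96 to 1.74 for luminal markers. The direction of both lists therefore did not depend on the choice among them. Less non-epithelial tissue of every kind stays open, since the 20 markers of other non-epithelial cells bright enough to show such a fall had a median log2 change of 0.090 with a 95% bootstrap interval (-1.26 to 0.98) above the limit of -1.36 but a lower quartile (-1.54) below it, some are also expressed by epithelium, the set was narrowed after all 38 measured had given -0.10, and the quartile condition was added after the interval was seen. A larger share of epithelial cells with unchanged luminal expression stays open, since 18.8% of the luminal markers (3 of 16) lay more than 2 SE from their median, between the shares set beforehand for and against it. The genotype, which may change either cell composition or expression within cells, was not tested apart from these.

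Neighbouring genes of distal chromosome 11 (GRCm38.p6) were higher in knockout tumours, a hypothesis found and tested on the same data. Over 65 genes from Rpl38 to Usp36 the median log2 change was 1.01, and the medians per tumour were 1.51, 1.17 and 0.27 in knockout 1, 2 and 3 and -0.14 to 0.20 in the controls, with 12 genes called higher and 2 lower, while the 56 genes from there to the chromosome end (Timp2 to Metrnl) lay at 1.24, -0.090 and 0.29 in knockout 1, 2 and 3. The tables argue against a chance order of changed genes (permutation p = 0.0080 for the highest window of 15 genes, 1000 shuffles). A cluster of epithelial genes stays open. Inside the segment 9 genes of families that every cell uses had a median of 0.87, against 0.01 over 307 elsewhere. The segment was picked for its high log2 changes and the genes elsewhere were not, so this difference cannot decide. Extra copies of the segment may be the cause and stay open, since DNA was not measured and regional control of transcription would look alike. In knockout 1, 2 and 3, 76.9%, 75.4% and 35.4% of the segment's genes lay at least 0.5 log2 units above the control mean. Because the segment was picked for high log2 changes, these shares cannot decide either. A second stretch past the limit, 16 genes of chromosome 13 from H3c10 to Vmn1r216, had a median of -0.78 (-0.30, -0.997 and -1.11 in knockout 1, 2 and 3), with 3 genes called lower and 43.8% of its genes above 0.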
